A study of Homo sapiens with 6 samples.

How the data were processed

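The data are one table of counts per gene symbol for 6 libraries of MOC2 cells, 3 control and 3 HuR knockout. The authors deposited whole-number counts; the tools STAR 2.7.1a and featureCounts and the build hg38 are listed, without role or order, per the submitters' processing notes. The row names are mouse symbols, which human gene models do not carry; the annotation the counts were made on, strand setting and filters are not given in the sources used here. The table has 21872 rows, of which 16325 have a count in any library. Genes that share reads with near-identical copies, and overlapping or antisense genes, may be split by the counting in ways that could not be checked. Libraries were assigned to groups by their titles, through the library names in the descriptions.

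The deposited counts were not all single read counts. In each of the 1704 rows with 0 in control library 1 and a count in another library, all values were multiples of 11, and no other row held only multiples of 11. Where control 1 was 0 and control 2 was not, the mean control 2 value was 16.4 as deposited and 1.49 after division by 11, against 1.97 for control 1 where control 2 was 0. No label describes a step that would give this. As deposited, these rows made up at most 0.0382% of a control library's total and 1.27%, 2.54% and 4.55% of the totals of knockout libraries 1, 2 and 3. The design written before the data were examined named the deposited counts. For the main test these rows were divided by 11, which departs from that design and was chosen after the values had been seen. The values as deposited, and the table without these rows, were run as alternatives and were also chosen after seeing the data. Of these rows, 76 entered the main test, where 73 changed, all 73 higher in knockout. A row with 0 in control 1 needed counts in the knockout libraries to pass the filter. The selection thus favoured higher values in knockout, and the shared direction is no separate result. As deposited, 526 entered.

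Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, robust dispersion estimates and the quasi-likelihood test of knockout against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are counts scaled per library by its TMM-scaled total (the usual CPM unit). Standard errors were taken from the fold change and the test statistic. The biological coefficient of variation was 28%. With 3 libraries per group each value rests on totals of 16158516 to 21294330 counts. Where a group was at 0, the fold is a bound against 3 counts over that group; where it held 1 to 3 counts, the ratio has an exact 95% Poisson interval. These cover counting error only. Every pair of libraries of one group differed by more than sampling noise (chi-square over genes), so no library was counted as a duplicate.

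Before the data were examined, 33 gene lists were fixed, of which 28 had at least 5 members tested. They were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 28 lists. Of these, 11 passed; with a correlation estimated from the data 0 passed, and 8 passed the rotation test fry, which asks whether a list's genes move, on balance, one way. Of these 8, 5 were among the 11: the fibroblast, mesenchymal, epithelial, NF-kB and chemokine lists. The other 3 were the WNT, apoptosis and YAP lists (fry adjusted p = 0.0013, 0.0169 and 0.0199). The interferon, MHC class I, HuR target, mitosis, replication and ribosomal lists did not pass fry (adjusted p = 0.142, 0.0633, 0.122, 0.384, 0.535 and 0.224). Some lists share members, so their results are not independent. Among others, Ccl20, Cxcl2 and Csf1 belong to the NF-kB and chemokine lists, and Cxcl2 also to the HuR target list. Col1a1 and Col3a1 belong to the fibroblast and mesenchymal lists. Unadjusted p-values of genes were under 0.05 for 5702 genes. The genes named in the text follow a rule fixed at the same time. It takes the ELAVL family and, among changed genes with a mean of at least 5 CPM, groups that do not overlap and a symbol that is not a predicted, clone, pseudogene or antisense name, the 10 with the largest and the 10 with the smallest log2 fold changes. From each list it takes up to 4 members with the smallest p, or 2 where no member passed. The rule named 137 genes, some of which are not reported here; others are said to have been picked afterwards or are members of the cell type lists.

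The procedure was tested on simulated counts for knockout against control, with 100 genes changed 2-fold and 100 changed 4-fold. With the gene-wise spread of the real libraries, over 12184 genes, 29% of the 2-fold and 86% of the 4-fold changes were recovered with 4 false calls. The changed genes were picked among well-counted genes, with equal numbers up and down. In the real libraries 35.7% of the genes tested changed, a far larger share. Recovery and false calls there may therefore differ from these values. Alternatives were DESeq2 1.42.0 size factors and its Wald test, library totals, upper quartile scaling, other filters on low counts, limma-voom, a test against a 1.5-fold change, a replicate block, leaving out the 10 genes with most counts, and leaving out each library. A correction for GC content and length needs mouse gene models, which were not used here. For a test of AU-rich elements, the 3′ untranslated regions of human genes with the same symbol were taken from GENCODE release 29. Figures were drawn with matplotlib 3.10.9.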

Results

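RNA was sequenced from MOC2 cells, a mouse oral squamous cell carcinoma line, in 3 control libraries and 3 libraries of cells in which the gene for HuR had been targeted with CRISPR/Cas9. HuR, the product of Elavl1, is an RNA-binding protein that binds AU-rich elements in 3′ untranslated regions and is known to stabilise many of the mRNAs it binds. The libraries are called knockout here after their genotype label, although their titles call them knockdown. Per the labels' protocols a single clone was isolated after transduction with lentiviral particles, and the series describes the samples as biological triplicates. Nothing says that the knockout libraries came from separate clones, so the p-values measure the spread between these libraries, part of which may be technical. The sample labels give human as the species, but the gene symbols are those of mouse and the series title names mouse cells.

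The deposited totals lay between 16164136 and 21294330 counts per library. In the 1704 rows with 0 in the first control library and a count elsewhere, all 3375 values above 0 were multiples of 11, against 8.17% of the 82660 values above 0 in the other rows. These rows were divided by 11 before any test, a choice made after the values had been seen; the numbers of changed genes with the values as deposited are given beside the main ones, and values of lists and named genes where the choice moved them by over 1.5 times or changed a call. After division the totals lay between 16158516 and 21294330. Log2 CPM correlated between control libraries at 0.987 to 0.992 (Pearson's r across genes, which are not independent replicates). Knockout libraries 1 and 2 correlated at 0.978, and knockout library 3 correlated with them at 0.924 and 0.931. The first principal component held 83.6% of the variance and separated knockout from control, and the second, with 10.5%, set knockout library 3 apart from the other knockout libraries.

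**Figure D1:**
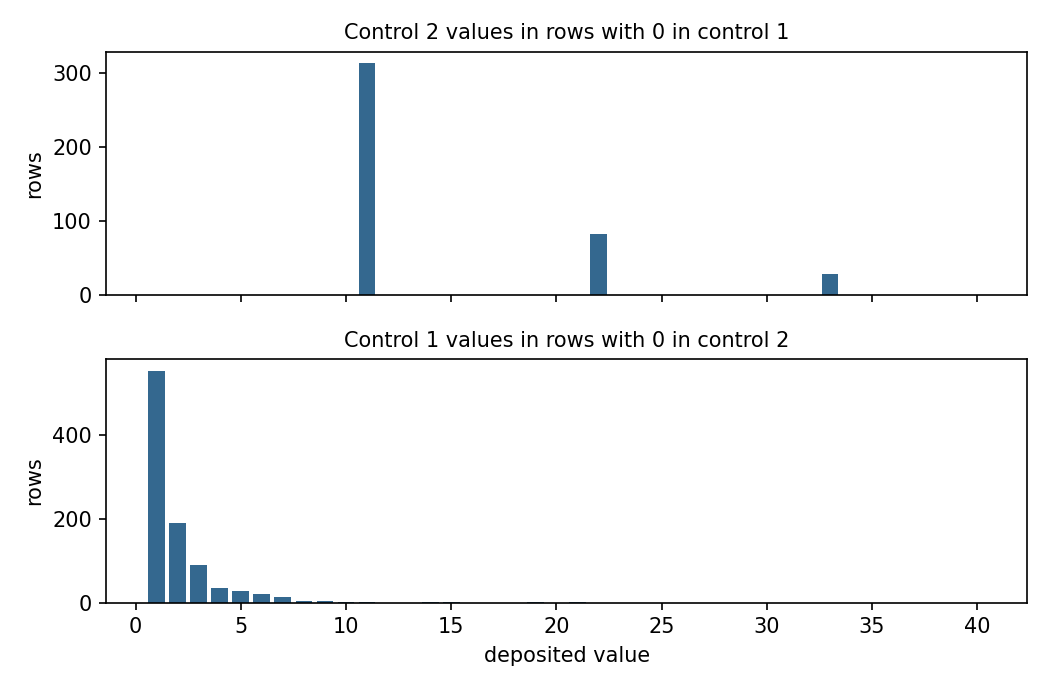
Number of rows (vertical axis) by deposited value (horizontal axis, values 1 to 40) for control 2 in rows where control 1 was 0 (top) and for control 1 in rows where control 2 was 0 (bottom). Where control 1 was 0 the lowest control 2 value was 11, held by 313 rows, whereas in the mirror rows 554 rows held a value of 1.

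The targeted gene was examined first. Elavl1 mRNA did not differ detectably between the groups: control libraries had 115 ± 6.57 CPM and knockout libraries 112 ± 5.7 CPM (SD, n = 3 each). The single libraries were at 107, 120 and 117 CPM in control and at 116, 114 and 105 CPM in knockout. The log2 fold change of Elavl1 was -0.04 (SE 0.111, 95% interval -0.30 to 0.23, adjusted p = 0.82 by edgeR's quasi-likelihood test). An edited mRNA can keep its level, so the mRNA level of Elavl1 neither checks nor contradicts the labels, and no protein measurement was analysed here. Of the neuronal paralogues, Elavl2 was at 0.341 CPM in control and 0.784 CPM in knockout (adjusted p = 0.117). Elavl3 and Elavl4 stood in rows divided by 11 and then held too few counts to test, with at most 0.0612 CPM in any library. With the values as deposited they reached at most 0.661 and 0.662 CPM and were tested (adjusted p = 0.985 and 0.636 by edgeR's quasi-likelihood test).

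The libraries labelled knockout differed widely from control. Of 12293 genes tested, 4392 (35.7%) changed, 2493 higher and 1899 lower in knockout, and 2785 of them changed at least 2-fold (1626 higher and 1159 lower). With the values as deposited, 4410 of 12759 genes changed, 2561 higher and 1849 lower, 2856 of them at least 2-fold. The groups did not overlap in CPM for 7082 genes, or 57.6%, where chance gives 10%. Leaving out control library 1, 2 or 3 lowered the number of changed genes to 2685, 2312 and 2358, and a test against a 1.5-fold change called 2280 genes.

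The genes with the largest increases were silent or nearly so in control, and all 10 stood in rows that had been divided by 11, so that their CPM in knockout and the bounds would be about 11 times higher with the values as deposited. Hspb7, a small heat shock protein of muscle, was at 327 ± 119 CPM in knockout and at 0 in every control library, at least 6210-fold higher against a floor of 3 counts over the control group (3550 CPM and 68100-fold as deposited). On the same basis Rtl3 was at least 1450-fold, Tnn (tenascin-W) at least 982-fold, Cacna1c, a subunit of a voltage-gated calcium channel, at least 971-fold, Agt (angiotensinogen) at least 702-fold, Clec1a at least 655-fold, Tfap2b at least 606-fold and Ogn (osteoglycin) at least 585-fold higher. Mgp, matrix Gla protein, had 911 ± 524 CPM in knockout, 26100 times its control level (counting interval 7210 to 215000). Kcnj15, a potassium channel, was 6350 times higher (1140 to 251000). Without knockout library 3, Rtl3 and Ogn no longer passed the test (adjusted p = 0.17 and 0.0523), and the bounds were 240-fold for Tnn and 444-fold for Agt. The control counts of Mgp and Kcnj15 came from control library 3, without which they were at least 12500-fold and 1520-fold higher. Leaving out control library 1 or 2 lowers each bound and ratio by over 1.5 times, since the control group's total over all genes is then smaller (for Hspb7, to 3930-fold and 4040-fold). These intervals cover counting error only, not the choice to divide. As deposited, the smallest value above 0 in these rows was 11, above the floor of 3 counts. If the rows were multiplied by 11, the bounds as deposited are too high and the intervals as deposited too narrow. With the values as deposited the ratios were 26000 for Mgp (17200 to 41500) and 6330 for Kcnj15 (3540 to 12700), the bounds of the other genes were 15900-fold for Rtl3, 10800-fold for Tnn, 10700-fold for Cacna1c, 7700-fold for Agt, 7180-fold for Clec1a, 6640-fold for Tfap2b and 6420-fold for Ogn, and 8 of the 10 largest increases were among those named here, with Serpina3n and Serpina3m in place of Mgp and Kcnj15.

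Among the largest decreases, 3 genes were at 0 in every knockout library. Xirp2, an actin-binding protein of striated muscle, fell from 31.1 ± 5.1 CPM and was at least 563-fold lower. Col4a3, a basement membrane collagen chain, was at least 221-fold lower, and Esm1 (endocan) at least 217-fold lower. Prom1, the stem cell marker CD133, was 926 times lower (166 to 36600) and Bex1 353 times lower (97.8 to 2920). The fitted decreases were 446-fold for Clca3b, 203-fold for the R-spondin receptor Lgr6, 202-fold for Ptprz1, 183-fold for Col4a4 and 139-fold for Ly6g (n = 3 libraries per group). Their sizes depended on single libraries with few counts. Without knockout library 1 they were 1770-fold for Clca3b, 475-fold for Ptprz1 and 428-fold for Col4a4. Without knockout library 2, Col4a4 was 120-fold lower. The bounds of Xirp2, Col4a3 and Esm1 were then 354-fold, 139-fold and 136-fold, as the knockout group's total over all genes was smaller. Prom1 was 583 times lower (105 to 23000) without knockout library 2 and at least 217-fold lower without knockout library 3, where Ly6g was 346-fold lower. Clca3b was 211-fold lower without control library 1.

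**Figure D2:**
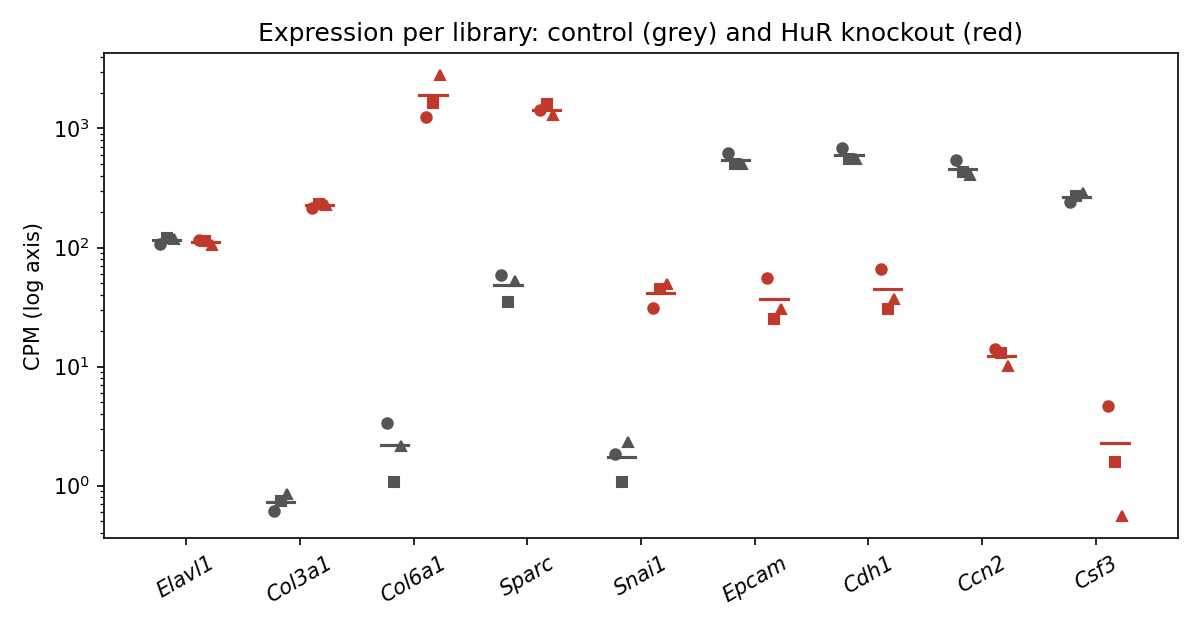
CPM on a log axis of 9 genes in each control (grey) and knockout (red) library; circles, squares and triangles are replicates 1, 2 and 3, and bars are group means. Elavl1 lay between 105 and 120 CPM in all 6 libraries, while the groups did not overlap for the other 8 genes.

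Most epithelial genes tested fell and most mesenchymal genes tested rose. Of 38 epithelial and keratinocyte genes tested, 25 fell, 3 rose and 10 did not pass; adjusted over the list alone, 27 fell and 4 rose. Epcam fell 14.7-fold, from 541 ± 67.7 to 36.9 ± 16 CPM, and Cdh1, which encodes E-cadherin, fell 13.4-fold, from 599 ± 73.1 to 44.7 ± 19.2 CPM. The desmosomal Pkp1 fell 6.73-fold. The list median was -2.12 on the log2 scale (adjusted p = 1e-06 by camera; adjusted p = 0.854 with an estimated correlation). Of the simple keratins, picked after their values were seen, Krt7, Krt8 and Krt18 fell, with log2 fold changes of -1.16, -1.04 and -1.93 (adjusted p = 0.0025, 0.0145 and 0.00103), Krt7 from 4207 to 1890 CPM. Krt19 was at 2821 ± 156 CPM in control and 3358 ± 784 CPM in knockout (adjusted p = 0.342). Some members of the list were higher in knockout. Krt15 was at 25.2, 25.4 and 77.3 CPM in knockout libraries 1, 2 and 3 and at most 1.03 CPM in control. Trp63 was at 1.53, 4.51 and 15.8 CPM there and at 0 in every control library. Its row had been divided by 11, so these CPM would be about 11 times higher as deposited. Of 26 mesenchymal genes, 20 rose, 3 fell and 3 did not pass (21 and 4 adjusted over the list alone). Col3a1, a fibrillar collagen chain, rose 309-fold, Sparc 29.7-fold to 1440 ± 155 CPM, the transcription factor Snai1 24-fold to 41.7 ± 9.34 CPM, and Twist2 4.13-fold (n = 3 each). The median of this list was 2.00 (adjusted p = 1.56e-05 by camera; adjusted p = 0.854 with an estimated correlation).

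Of 20 fibroblast markers, 11 had enough counts to test. Of these, 10 rose and 1 did not pass, and the same numbers held adjusted over the list alone. A marker near 0 in control could enter the test only through its knockout counts. The filter thus favoured markers that rose, which limits what these numbers, the list median and its set test show. Col6a1 rose 861-fold to 1900 ± 815 CPM, Col6a2 1970-fold to 1050 ± 309 CPM (3400-fold without control library 1), and Mgp and Col3a1, given above, belong to the same list. The median was 8.27 (adjusted p = 1e-06 by camera; adjusted p = 0.854 with an estimated correlation), 5.62 over 13 markers with the values as deposited and 6.95 over 10 without the divided rows. Col1a1 was higher too, at 199, 121 and 119 CPM in knockout libraries 1, 2 and 3 and at most 4.44 CPM in control. So were Col6a3 (1020, 573 and 1900 CPM) and Pdgfrb (12.6, 51.9 and 50 CPM). Some other abundant fibroblast transcripts stayed near 0. In knockout library 3, Col1a2 was at 0.122 CPM, Dcn at 0.796 CPM and Postn at 0.245 CPM (1.32 CPM for Col1a2 and 2.65 CPM for Postn as deposited). Lum had no count in any library. Of 16 endothelial markers, 4 had enough counts to test. Of these, 3 rose and 1 did not pass (4 rose adjusted over the list alone). The VEGF receptor Flt1 rose 9.17-fold to 210 ± 48.2 CPM, Plvap 11.2-fold (from 0.157 to 1.8 CPM) and Eng 2.49-fold. Egfl7 had an adjusted p of 0.0631 (0.00662 without knockout library 3). The call of Eng was lost without control library 1, 2 or 3 (adjusted p = 0.0577, 0.0706 and 0.0646). Too few members were tested for the set test. With the values as deposited 7 were tested, 5 rose, among them Vwf and Sox18 (adjusted p = 0.00704 and 0.0229), the median was 3.19 where it had been 2.26, and the list passed (adjusted p = 0.00202 by camera). It passed too, with 5 members tested, without control library 1, 2 or 3 (adjusted p = 0.012, 0.00672 and 0.00816, with 2 members higher each time) or knockout library 1 (0.00497, with 4 higher). The markers not tested in the main fit, Cdh5, Pecam1, Kdr and Tek among them, stayed under 1 CPM in every library. Vwf and Sox18 were among them too, after division by 11.

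**Figure D3:**
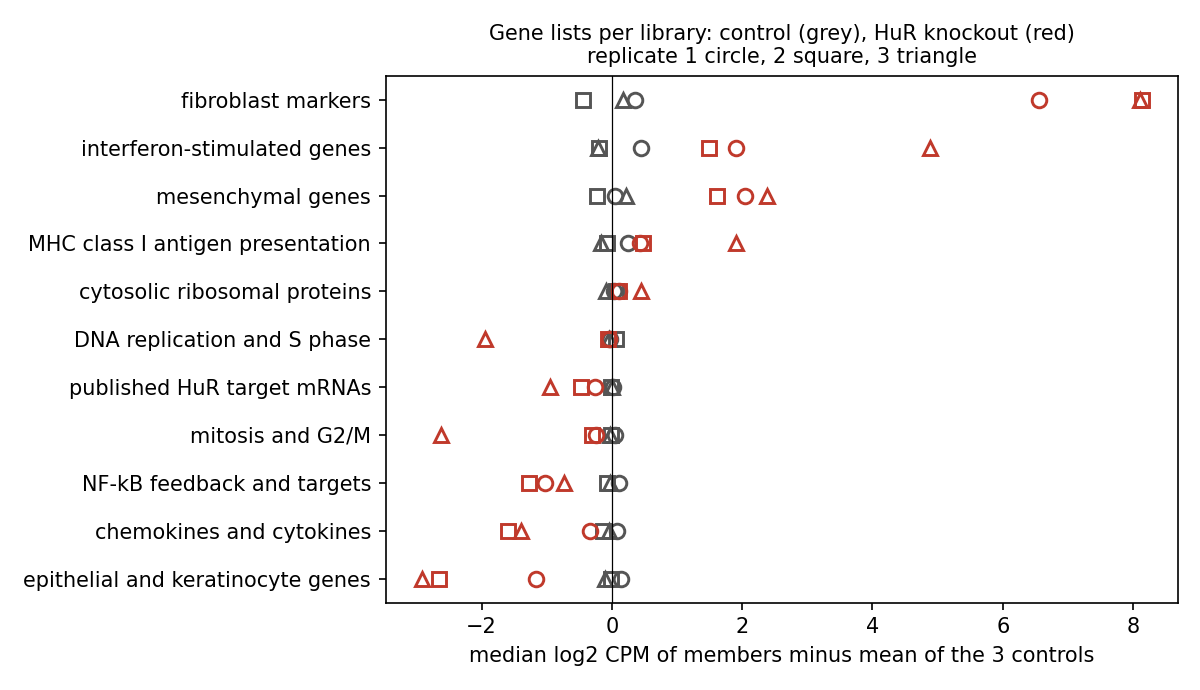
Median over the members of each list of log2 CPM minus the mean of the 3 controls (horizontal axis), for the 11 lists past the set test; control libraries are grey and knockout libraries red, with circles, squares and triangles for replicates 1, 2 and 3. Knockout library 3 lay at 4.89 for interferon-stimulated genes, -2.63 for mitosis genes and -1.94 for DNA replication genes, where knockout libraries 1 and 2 lay at 1.91 and 1.49, at -0.24 and -0.31, and at -0.04 and -0.06.

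Interferon-stimulated genes rose. Of 49 tested, 28 rose and 21 did not pass, and 35 rose adjusted over the list alone; DESeq2 called 23 members and limma-voom 5. Without control library 1, 2 or 3, 7, 6 and 6 rose. Ifitm3, an antiviral membrane protein, rose 22.4-fold from 19.2 ± 4.06 to 431 ± 240 CPM, Lgals3bp 40.8-fold, Ifi27 14.1-fold and the DNA sensor Ifi204 9.53-fold. The median was 3.68 (adjusted p = 2.41e-06 by camera; adjusted p = 0.854 with an estimated correlation). Knockout library 3 stood highest; without it the median was 1.78, with 30 genes higher and 2 lower (adjusted p = 1.1e-05 by camera), and Lgals3bp and Ifi204 rose 23.5-fold and 6.2-fold. Without control library 1, Lgals3bp rose 83.5-fold and Ifi27 24.6-fold. Of 21 genes of MHC class I antigen presentation, 10 rose and 11 did not pass (12 rose adjusted over the list alone; DESeq2 called 12 and limma-voom 6). The peptide transporter genes Tap1 and Tap2 rose 18.4-fold and 10.2-fold, the immunoproteasome gene Psmb8 17.1-fold and the class I transactivator Nlrc5 11.5-fold. Without knockout library 3 these were 8.33-fold, 5.71-fold, 8.52-fold and 4.94-fold, and without control library 1 Tap1 and Psmb8 rose 28-fold and 33.7-fold. Their median was 1.03 (adjusted p = 0.00195 by camera; adjusted p = 0.854 with an estimated correlation) and 0.49 without knockout library 3, when 13 rose; without control library 1, 2 or 3, 6, 2 and 1 rose. Nlrc5 then had an adjusted p of 0.0611, 0.0557 and 0.0667, Psmb8 of 0.0585 without control library 2 and 0.0517 without control library 3, and Tap1 of 0.0517 without control library 3. Of 22 innate RNA and DNA sensing genes, 7 rose and 2 fell, and the list did not pass (adjusted p = 0.226 by camera); Ticam1 rose 3.14-fold, Traf3 fell 2.21-fold and Ikbke fell 2.34-fold. The numbers were the same adjusted over the list alone; without knockout library 3, 9 rose and 4 fell, and without any 1 control library 2 rose and 2 fell.

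NF-kB feedback genes and several secreted factors fell. Of 31 NF-kB feedback and target genes, 16 fell, 2 rose and 13 did not pass (18 and 4 adjusted over the list alone). Without control library 1, 2 or 3, 11, 10 and 11 fell and 1 rose; without knockout library 2, 14 fell and 4 rose, and 17 fell and 1 rose without knockout library 3. Ccl20 fell 74.2-fold and Ptgs2, which encodes cyclooxygenase-2, 3.97-fold, from 371 ± 28 to 93.3 ± 23.4 CPM; Birc3 was 77.6 times lower (21.5 to 641), and Csf1 rose 2.48-fold. Ccl20 was 174-fold lower without knockout library 1 and 48.7-fold lower without knockout library 2, where Birc3 was at 0 and at least 32.6-fold lower. The median was -0.88 (adjusted p = 0.000248 by camera; adjusted p = 0.854 with an estimated correlation). Of 26 chemokines and cytokines, 11 fell, 5 rose and 10 did not pass (12 and 6 adjusted over the list alone). Csf3, the neutrophil growth factor G-CSF, fell 116-fold from 267 ± 23.6 CPM, Il23a 39.8-fold, Cxcl16 23.6-fold and Lif 16.1-fold; without knockout library 1 Csf3 was 244-fold lower. Their median was -1.07 (adjusted p = 0.0275 by camera; adjusted p = 0.854 with an estimated correlation). This list lost its call without control library 1 (median -0.286, adjusted p = 0.0573), knockout library 2 (-0.662, 0.1) or knockout library 3 (-1.02, 0.0569); without knockout library 1 the median was -1.74, and without control library 2 or 3, 3 rose. Of 15 immune checkpoint ligands, 4 rose and 4 fell (5 and 4 adjusted over the list alone): Cd47 rose 2.65-fold and Lgals9 13.7-fold (25.9-fold without control library 1), Nectin2 fell 3.6-fold and Cd276 1.77-fold. Their median (-0.015) and mean (0.77) differed in sign, the median lay between -0.415 (without knockout library 3) and 0.192 (without control library 1), and the list did not pass (adjusted p = 0.832 by camera, direction down). Of 31 apoptosis regulators, 7 rose and 10 fell (7 and 11 adjusted over the list alone; adjusted p = 0.519 by camera); without control library 1, 2 or 3, 3, 1 and 2 rose and 3, 3 and 4 fell, and without knockout library 1 or 2, 6 and 4 fell. Casp12 rose 8.77-fold, while Bcl2 fell 2.09-fold and the death receptor gene Tnfrsf10b 2.13-fold.

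Of 39 mRNAs published as HuR targets, 11 fell, 4 rose and 24 did not pass, with the same numbers adjusted over the list alone. Plau, the urokinase gene, fell 9.91-fold, Egfr 6.92-fold from 80 ± 13.3 to 11.6 ± 5.66 CPM, and Ptgs2 fell as given above, while Snai1 rose. The median was -0.57 (adjusted p = 0.0367 by camera; adjusted p = 0.854 with an estimated correlation). The call was lost, with little change of the median, without control library 1 (median -0.557, adjusted p = 0.0531), without knockout library 2 (-0.591, 0.0708) and without the 10 genes with most counts (-0.549, 0.0536). Without knockout library 3 the median was -0.255, with 15 lower and 5 higher (adjusted p = 0.0446 by camera); without control library 1, 2 or 3, 8, 6 and 7 fell and 1 rose. Of 27 other proteins that bind 3′ untranslated regions, 1 rose and 3 fell (adjusted over the list alone, 1 fell), and the list did not pass (adjusted p = 0.323 by camera). Leaving out knockout library 3 gave 7 lower, and leaving out any 1 control library gave 1 lower and 0 higher. The RNase gene Zc3h12a fell 3.23-fold, Ybx1 1.73-fold and Celf1 1.47-fold, and Zfp36l2 rose 1.53-fold. Without control library 1, 2 or 3 the last 3 lost their calls (adjusted p = 0.0952, 0.0987 and 0.084 for Ybx1, 0.0725, 0.142 and 0.138 for Celf1, and 0.104, 0.113 and 0.0741 for Zfp36l2), as did Ybx1 without knockout library 2 (0.0552) and Celf1 without knockout library 1 (0.0887) and with the values as deposited (0.0502).

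Among targets of growth pathways, Ccn2 (CTGF), a target of YAP and TEAD, fell 37-fold from 458 ± 71.6 to 12.4 ± 2.04 CPM. Ankrd1 fell 7.84-fold, Wwc1 4.43-fold and Ajuba 3.98-fold; of 24 such genes 6 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.226 by camera; 0.0446 without knockout library 3, when 10 fell). Of 12 WNT targets, 5 rose and 4 fell (6 and 4 adjusted over the list alone; adjusted p = 0.519 by camera); without control library 1 or 2, 3 rose and 2 fell, and without control library 3, 4 rose and 1 fell. With the values as deposited, 14 were tested and 6 rose. The feedback inhibitors Nkd1, Axin2 and Notum rose 50.2-fold, 14.2-fold and 20.2-fold, and Znrf3 fell 1.7-fold. Of 36 immediate early and MAPK feedback genes, 10 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.588 by camera; 4 and 3 without control library 2, 5 and 3 without control library 3); Etv1 rose 6.22-fold, Spry1 3.04-fold and Spred1 1.99-fold, and Hbegf fell 6.18-fold. Of 27 matrix proteases and inhibitors, 10 rose and 7 fell (12 and 9 adjusted over the list alone; adjusted p = 0.594 by camera; 6 rose without control library 2 or 3). Serpine2 rose 24-fold, Hpse 3.73-fold and Adam10 2.54-fold, and Plau fell. Of 30 hypoxia and angiogenesis genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone; adjusted p = 0.148 by camera, 0.0446 without knockout library 3 and 0.0441 with a stricter filter on low counts and all 6 libraries; 8 and 7 rose without control library 2 and 3). Epas1, which encodes HIF-2α, rose 87.9-fold and Ddit4 5.45-fold, Pdgfb fell 35-fold, and Lox was 151 times lower (27 to 5950). Without knockout library 3 Epas1 rose 44.3-fold, and without knockout library 1 Pdgfb fell 60.6-fold. Lox was 91.3 times lower (16.4 to 3600) without control library 1 and at least 31.6-fold lower without knockout library 2.

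Cell cycle lists lay lowest in knockout library 3. The median of 39 mitosis and G2/M genes was -0.71 (adjusted p = 0.00283 by camera; adjusted p = 0.921 with an estimated correlation), but only Kif23 passed the gene test, falling 3.53-fold; Nek2, Ect2 and Espl1 had adjusted p of 0.117, 0.15 and 0.192, and of 0.000674, 0.000755 and 0.00346 without knockout library 3. Adjusted over the list alone 0 members passed in edgeR, with 1 at an unadjusted p under 0.05, 2 called by DESeq2 and 1 by limma-voom. The median without that library was -0.26, with 16 genes lower and 1 higher, and the list still passed (adjusted p = 0.000782 by camera); 0 members passed the gene test without control library 1, 2 or 3 or knockout library 2 (adjusted p of Kif23 0.105, 0.102, 0.0977 and 0.0929). The median of 44 DNA replication genes was -0.44 (adjusted p = 0.0274 by camera; adjusted p = 0.921 with an estimated correlation). The single called member, the ribonucleotide reductase subunit Rrm2, rose 2.05-fold, against the direction of the list; Orc1, Pola2 and Mcm10 had adjusted p of 0.102, 0.194 and 0.249, and of 0.000266, 0.0292 and 0.00263 without knockout library 3. Adjusted over the list alone 0 passed in edgeR, with 2 at an unadjusted p under 0.05, 2 called by DESeq2 and 1 by limma-voom. The median without that library was -0.04, with 9 genes lower and 3 higher, and the call was lost (adjusted p = 0.53); without knockout library 1 or 2 it was -0.671 and -0.738, and leaving out control library 1, 2 or 3 or knockout library 1 or 2 left 0 members called (adjusted p of Rrm2 0.127, 0.114, 0.142, 0.0939 and 0.11). Of 9 replication-dependent histone genes, H1f2 rose 2.13-fold and 8 did not pass, among them H2bc4, H3c3 and H1f3 (adjusted p = 0.677 by camera); adjusted over the list alone 0 passed in edgeR, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2 and by limma-voom. The call of H1f2 was lost without control library 2 or 3 (adjusted p = 0.146 and 0.0927) or knockout library 1 or 2 (0.0746 and 0.0987), and with the values as deposited (0.0501), and H2bc4 passed without control library 1 (0.0492). Of 27 p53 targets, 6 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.805 by camera; 8 and 8 without knockout library 3, 3 and 3 without control library 1 or 2); Sulf2 rose 320-fold (210-fold without knockout library 3), Pltp 3.22-fold and Phlda3 2.62-fold, and Aen fell 2.14-fold.

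Of 75 cytosolic ribosomal protein genes, Rps21 rose 1.34-fold (adjusted p = 0.05 after rounding) and 74 did not pass; Rpl39, Rpl37a and Rpl27a had adjusted p of 0.0588, 0.064 and 0.0712, and of 0.0177, 0.0279 and 0.0203 without knockout library 3. The list median was 0.23 (adjusted p = 0.0146 by camera; adjusted p = 0.921 with an estimated correlation), and the call was lost without control library 3 (median 0.162, adjusted p = 0.174) or knockout library 3 (0.122, 0.0677, with 13 members higher); 2 were higher without knockout library 1 (Rpl39 among them, adjusted p = 0.05), and 0 without control library 1, 2 or 3 or knockout library 2 (adjusted p of Rps21 0.115, 0.15, 0.221 and 0.108) or with the values as deposited (0.0517). Adjusted over the list alone 0 passed in edgeR, with 10 at an unadjusted p under 0.05, 6 called by DESeq2 and 1 by limma-voom. Of 48 nuclear genes of oxidative phosphorylation, 6 rose and 1 fell (adjusted p = 0.366 by camera), with Ndufa6, Ndufb10 and Ndufv2 higher by 1.77-fold, 1.51-fold and 1.33-fold. Adjusted over the list alone 0 of these passed in edgeR, with 11 at an unadjusted p under 0.05, 10 called by DESeq2 and 7 by limma-voom. Of 21 glycolysis genes, 6 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.548 by camera). Aldoc rose 7.05-fold, Ldhb 5.37-fold and Pfkm 1.97-fold, and the lactate exporter Slc16a3 was 60.9 times lower (20.8 to 295). Slc16a3 was 33.9 times lower (11.6 to 164) without control library 1 and 115 times lower (20.6 to 4540) without knockout library 2. Both lists passed without knockout library 3 (adjusted p = 0.00619 and 0.00464), with 17 genes higher and 1 lower and with 16 higher and 2 lower. Of the first list, 1, 0 and 0 rose without control library 1, 2 and 3, and 3 without knockout library 1 or 2. The calls of Ndufb10 and Ndufv2 were lost without control library 1, 2 or 3 (adjusted p = 0.0662, 0.0842 and 0.102, and 0.0907, 0.122 and 0.164), that of Ndufv2 also without knockout library 1 or 2 (0.0745 and 0.072), and that of Ndufa6 without control library 2 or 3 (0.0683 and 0.0634). Of the second, 1 fell without control library 1 or 3. All 13 mitochondrially encoded mRNAs were listed at 0 in every library.

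Stress and lipid genes moved in both directions. Of 29 NRF2 and oxidative stress genes, 7 rose and 4 fell, also adjusted over the list alone; their median (-0.05) and mean (0.15) differed in sign (adjusted p = 0.999 by camera). Their median was 0.0387 without knockout library 3, with 12 higher and 6 lower; without control library 1, 2 or 3, 4, 3 and 2 rose. Gclc, a subunit of the enzyme that limits glutathione synthesis, rose 7.49-fold and Gstm1 9.06-fold, while Osgin1 fell 9.26-fold and Txnrd1 2.45-fold. Of 22 heat shock proteins, 2 rose and 6 fell (2 and 7 adjusted over the list alone; adjusted p = 0.0894 by camera); without knockout library 3, 3 rose and 11 fell, and without control library 1, 2 or 3, 1, 2 and 3 fell. Dnajb4 rose 6.34-fold and Bag3 1.57-fold; Hsph1 fell 2.88-fold and Hspa8 1.49-fold (adjusted p = 0.0565 and 0.0527 without control library 1 and 2). Of 35 unfolded protein and integrated stress response genes, 5 rose and 30 did not pass, also adjusted over the list alone (adjusted p = 0.42 by camera). Leaving out knockout library 3 gave 12 higher, knockout library 2 gave 10 higher, knockout library 1 gave 6 higher and 2 lower, and control library 1 or 2 gave 2 higher. They included Vldlr (4.03-fold), Dnajb9 (3.72-fold), Dnajc3 (2.00-fold) and Xbp1 (1.69-fold). Vldlr and Dnajb9 lost their calls without control library 1 (adjusted p = 0.0626 and 0.0519) or control library 2 (0.0713 and 0.0573). Of 30 cholesterol and fatty acid synthesis genes, 2 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.588 by camera). Of these, 7 rose and 4 fell without knockout library 3; 1 rose without knockout library 2 or any 1 control library, and 2, 0 and 0 fell without control library 1, 2 and 3. Acss2 rose 5.41-fold and Srebf1 1.75-fold, and Hsd17b7 and Acaca fell 2.36-fold and 1.52-fold. The call of Srebf1 was lost without control library 1, 2 or 3 or knockout library 2 (adjusted p = 0.0837, 0.0902, 0.0735 and 0.0514), that of Hsd17b7 without control library 2 or 3 (0.0656 and 0.0668) and that of Acaca without control library 2 or 3 or knockout library 2 (0.0757, 0.0788 and 0.0592).

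Markers of immune cells were nearly absent. Of 20 macrophage and myeloid markers, 3 had enough counts to test (6 with the values as deposited, where 1 rose and 1 fell). Mrc1 fell 90.3-fold from 21.7 ± 5.15 CPM (191-fold without knockout library 1), Cd14 rose 1.57-fold (adjusted p = 0.0585, 0.124, 0.101 and 0.063 without control library 1, 2 and 3 and knockout library 2), and Cd68 was at 36.9 CPM in knockout library 3 and at 1.76 to 5.8 CPM in the other libraries (adjusted p = 0.248). Of the T and NK cell markers 1 was tested: Lck was at 1 CPM in control and 0.653 CPM in knockout (adjusted p = 0.336). With the values as deposited 3 were tested and Zap70 rose, from 0 to 2.75 CPM (adjusted p = 0.00485).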

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

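Alternatives were chosen before the data were examined, except the 2 handlings of the rows divided by 11 and the list members under these or with one library left out, chosen after. The number of genes changed, 4392, stayed within 1.5 times under DESeq2 size factors, library totals, upper quartile scaling, other filters, limma-voom and the DESeq2 Wald test (5283), with the values as deposited (4410) and without the rows in question (4323). Leaving out one library gave 2312 to 6021 changed genes, 1166 to 3178 higher, 1130 to 2843 lower, 1961 to 3092 changed at least 2-fold, and 9 to 12 lists past the set test. The lowest numbers of changed genes came without a control library and the highest count of changed genes, 6021, without knockout library 3; the cause was not tested. A test against a 1.5-fold change gave 2280 genes, 1307 higher and 973 lower, since it asks for larger changes. With an estimated correlation, 0 of the 11 lists passed camera. Elavl1 ranged from -0.0888 to 0.0061 (log2) when one library was left out and crossed 0 without knockout library 3, with adjusted p from 0.668 to 0.962 over all alternatives; Cd68 turned from 1.84 to -0.67 there (2.36 without knockout library 2), so its higher value rested on that library. The same-numbered libraries correlated in their deviations at -0.0487, 0.256 and 0.0219, and the other pairs at -0.249 to 0.192. With so few libraries these values do not decide whether same-numbered libraries were handled together. A replicate block gave 3591 changed genes (1976 higher, 1615 lower), 2597 changed at least 2-fold and 11 lists. Over all alternatives, named genes kept direction and call in 2163 of 2276 cases, lost the call in 92 and gained it in 19. Most of them were named for small p or large changes in these same data, so these numbers do not carry over to all genes. The correction for GC content and length was not run. Depth limits the genes at under about 1 CPM, where a group holds few counts.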

Other observations

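The tests in this part were chosen after the results were seen, except the test of AU-rich elements and the other splits of the libraries.

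Of the 10 ways to split the 6 libraries into 3 and 3, the real split gave 4392 changed genes and the highest of the others gave 0; 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

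In rows with 0 in control 1, 100% of the values above 0 were multiples of 11. This share prompted the idea that the rows had been multiplied by 11 before deposit, so it does not test that idea. A true rise of genes silent in control 1 was weighed too. It would leave the controls alike, but the values of control 2 and 3 where control 1 was 0 were at least 8.1 times those of the mirror rows. The values do argue against single read counts in these rows, as 8.17% of the values above 0 in the other rows were multiples of 11. Which step gave them, a multiplication by 11 or another, stays open.

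The gain of fibroblast and mesenchymal genes and the loss of epithelial genes were weighed against a mixture of cells. Fibroblasts would bring all of their abundant transcripts. The median of Col6a1, Col6a2, Col6a3 and Mgp, 1110 CPM in knockout, was 2360 times the highest of Col1a2, Lum, Dcn, Postn and Fap (912 times with the values as deposited). Both sets were picked from the fibroblast list after its values had been seen, so the ratio does not count against fibroblasts. Col1a1, in neither set, was at 199, 121 and 119 CPM in knockout libraries 1, 2 and 3. The ratio shows only that the rise did not cover all fibroblast markers. A lower share of epithelial cells would lower their genes alike only if the other cells expressed none of them. Of the 32 epithelial genes with at least 5 CPM in control, 21 (65.6%) had an interval apart from the median of -2.39. What other cells would express is not known here, so these unequal falls do not decide against a mixture. A difference between the clone or line and the control cells other than loss of HuR could not be told apart from loss of HuR, since the knockout libraries, per the labels, follow isolation of a single clone. Elavl1 mRNA, at 97.5% of control, does not decide this, as an edited mRNA can keep its level. A biological effect of HuR loss stays open with it.

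Knockout library 3 stood apart in interferon, mitosis, replication and glycolysis genes. Cd68 was also high there, at 36.9 CPM. Immune cells would bring their other abundant transcripts, and 8 genes of immune cells (Ptprc, Adgre1, Itgam, Tyrobp, C1qa, C1qb, C1qc and Spi1) together held 0 counts there. The 8 were picked after the values had been seen. Other markers were highest in that library: Ctss at 0.857, Cd52 at 0.306 and Lyz2 at 0.184 CPM (3.31 for Cd52 and 1.99 for Lyz2 as deposited). The 0 counts cover these 8 genes only and do not exclude immune cells. Depth was tested by thinning all libraries to 16158516 counts. The interferon list median of library 3 was then 4.84 (4.89 before), still 2.89 above the higher of the other knockout libraries. Library 3 already held 16746166 counts, so thinning changed it little. The mitosis, replication and glycolysis lists were not compared after thinning. No biological explanation was tested, since the labels give no group within the knockout libraries.

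HuR is known to stabilise mRNAs with AU-rich elements, so their genes were predicted to be lower in knockout. Human 3′ untranslated regions with the same symbol were found for 10839 genes (88.2% of those tested). Genes with at least 2 AUUUA pentamers had a median log2 fold change 0.195 below that of genes with none, in bins matched on length and expression (difference -0.195, 95% bootstrap interval -0.283 to -0.137). The bootstrap resampled genes within bins, so the interval covers the spread between genes and not between libraries. This comparison was not repeated with a library left out. The prediction also asked for a larger difference than for every other pentamer of the same composition, and AUUUA ranked 5 of 10, with UUAAU at -0.229. The difference may follow AU content rather than the element, and whether HuR, another property of AU-rich mRNAs or a GC bias of the libraries lies behind it cannot be told apart here, as human sequences stand in for mouse ones.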
